A study of Mus musculus with 16 samples.

How the data were processed

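Total RNA of AtT-20 cells, depleted of ribosomal RNA, was sequenced as 50 bp paired ends, per the labels' protocols. Groups and replicate numbers were taken from the labels: Neo and Pax7 with 2 libraries each, and ER-Pax7 at 0, 12, 24 and 96 h of 4-hydroxytamoxifen with 3 libraries each. The labels do not say that replicates are separate cultures, so p-values measure the spread between these samples, which may be technical. Neo and Pax7 are 1 pair of cell populations, so their comparison cannot separate Pax7 from other differences between those populations.

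Reads were mapped to mm10 (GRCm38), and TopHat, HOMER and edgeR are named, without versions, per the submitters' processing notes. For the ER-Pax7 table the authors counted reads over the exons of each RefSeq gene with HOMER analyzeRepeats.pl, without a strand option, and the deposited signal values are those reads scaled so that each library sums to the same total of about 7213570, per the file headers and the values. For the Neo and Pax7 table the authors counted reads over whole gene bodies, introns included, and deposited them as FPKM, rescaled to a common total of about 120820, per the file headers and the values. The authors' deposited log2 folds and the authors' deposited p-value and FDR columns come from HOMER's getDiffExpression.pl, which ran edgeR, per the file headers. They were used only for comparison. For Pax7 against Neo, 7143 of 7178 genes whose 4 FPKM values round to 0 have a log2 fold of exactly 0 in the authors' deposited table. However, of 39 patterns of rounded values shared by at least 10 genes, only 2 have a single deposited log2 fold, so whether that test ran on rounded values is left open. Without strand, overlapping and antisense genes cannot be told apart, and reads of near-identical gene copies may be split between them.

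Neither table holds raw counts, so the edgeR test planned before the data were examined was replaced by limma on a log scale, and the filters and pseudocounts were set in the units found. Low values of the ER-Pax7 table are whole multiples of the worth of 1 read (100% whole within a tolerance of 0.1 reads), which gave back whole reads. The recovered totals were 61.4 M, 62.0 M and 88.7 M read mates at 0 h, 70.1 M, 69.8 M and 63.5 M at 12 h, 62.4 M, 67.3 M and 68.8 M at 24 h, and 72.1 M, 68.0 M and 80.7 M at 96 h. In these, 55.6% to 57.5% of low values were even numbers of mates, so mates of 1 fragment are in part counted separately. Among FPKM values of short genes, 88.6% to 97.6% were whole multiples, against 5.21% to 6.77% by chance, for an estimated depth of 54.7 M and 49.6 M in Neo and 44.2 M and 49.3 M in Pax7. Reads carry no molecular identifiers, so precision judged from them covers counting error only; the errors given here are the spread between libraries. Between 17185 and 17653 genes were above 0 in the ER-Pax7 libraries and between 16174 and 16553 in the others, of 24063 genes in each table. Chromosome positions are mm10, counted from 1.

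Genes were tested if their value reached 1 scaled exon read in at least 3 libraries (15188 genes) or 0.1 FPKM in at least 2 (13393 genes). Values were divided by TMM factors (edgeR 4.0.16), a pseudocount of 1 or 0.1 was added, and log2 values were tested with limma 3.58.1 (empirical Bayes with trend; R 4.3.3), with the 12 ER-Pax7 libraries in a single model. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Means and SD are of values divided by the same factors, except where deposited values are named. Exact permutation cannot go below p = 0.1 with 3 against 3 libraries or 0.333 with 2 against 2, so it was not used. The 7 comparisons were Pax7 against Neo, 12, 24 and 96 h against 0 h, 24 h against 12 h, 96 h against 24 h, and all 4 times.

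A set of 20 gene lists was fixed before the data were examined: melanotrope markers, corticotrope markers, other pituitary hormone lineages, pituitary progenitor, peptide processing and secretory granule, skeletal muscle, neuronal adhesion and ion channels, cell cycle, CDK inhibitors, oestrogen response, cholesterol synthesis and uptake, unfolded protein and amino acid stress, immediate early, interferon response, Notch, Wnt, chromatin regulators, extracellular matrix, epithelial and immune cell genes. Lists with at least 3 tested members were tested with limma camera (preset correlation 0.01, and estimated correlation) and fry, adjusted over lists within a comparison. No list was called with an estimated correlation in any comparison. The named genes follow a rule also fixed then: Pax7 and Esr1, then the 10 highest and 10 lowest log2 folds (Pax7 against Neo and 96 h) or the 6 highest and 6 lowest (12 and 24 h) among called genes with a mean log2 CPM of at least 1, no overlap of groups and a named symbol. Members of pituitary marker lists and the members with the smallest adjusted p of other lists were added. Genes named for 24 h against 12 h, genes called in opposite directions by the systems and the Pcsk2 antisense genes fall outside the rule and were picked after their values were seen. Some genes that meet the rule are not reported here.

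Replicates were compared by a chi-square of recovered reads over genes with at least 20 reads. It gave 5.82 to 50.4 per degree of freedom, and the pairs with 12 h replicate 2 were the highest, at 44.6 and 50.4. Of genes above 0 in Neo or Pax7 libraries, 1984 of 16723 and 1844 of 17160 had values above 0 that were equal to the 2 decimals printed in both replicates, which low genes also reach by rounding. No pair was treated as a single library. The fits were tested on simulated data with 200 changed genes. For 96 h against 0 h, with an assumed dispersion of 0.002, 83.6%, 92.5% and 98.5% of genes changed 1.5-, 2- and 4-fold were recovered and 7.58% of calls were unchanged genes. As this was over 5%, a run with the dispersion estimated from recovered reads was added; it recovered 77.6%, 88.1% and 93.9% with 4.42% of calls unchanged. For Pax7 against Neo, errors were drawn with the spread that the fit itself gave each gene. There 58.2%, 85.1% and 83.3% were recovered and 3.82% of calls were unchanged genes. A share near 5% is largely built into that setting, so it does not check the calls made on the real libraries.

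Alternatives were median-of-ratios scaling (DESeq2 1.42.0), library totals, no filter and stricter filters (7.21 scaled exon reads or 1 FPKM), other pseudocounts (0.1 and 5, or 0.01 and 0.5), edgeR and DESeq2 on recovered reads, the replicate number as a block, each library left out, only the groups compared in the fit, totals without Rn45s, and a minimum change of 2-fold. Chance overlap through shared 0 h libraries was simulated in 20 draws. Of the genes called in the authors' deposited table at an FDR under 0.05 (196 higher and 238 lower at 12 h, 330 and 558 at 24 h, 1288 and 1496 at 96 h), 430 of 434, 888 of 888 and 2755 of 2784 that were also tested here were called in the same direction. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.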

Results

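RNA was sequenced from AtT-20 cells, a mouse corticotrope tumour line that makes the hormone precursor pro-opiomelanocortin (Pomc). The comparisons asked which transcripts change when these cells make Pax7, a pioneer transcription factor that specifies the melanotrope, the other Pomc-producing cell of the pituitary. The 16 libraries form 6 groups. Neo control cells and cells with constitutive Pax7 were each sequenced in 2 libraries. Cells carrying ER-Pax7, a fusion of Pax7 to an oestrogen receptor part that 4-hydroxytamoxifen activates, were sequenced at 0, 12, 24 and 96 h of the compound, with 3 libraries at each time. The 12 ER-Pax7 libraries held between 61.4 M and 88.7 M counted read mates (M, mega), and the 4 Neo and Pax7 libraries an estimated 44.2 M to 54.7 M. Neo and Pax7 values are FPKM over gene bodies and ER-Pax7 values are scaled exon reads, so every test stayed within its own table and no level can be compared across them.

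The construct genes were read first. Pax7 (RefSeq NM_011039, mm10 chromosome 4, 139738081 to 139832968) had deposited values of 0 and 0.01 FPKM in the Neo libraries and 2.39 and 2.38 FPKM in the Pax7 libraries. In the ER-Pax7 cells its transcript, which includes the fusion, stood at 1725 ± 43.2 scaled exon reads at 0 h, 1741 ± 59.0 at 12 h, 1759 ± 103 at 24 h and 1895 ± 24.8 at 96 h (mean ± SD, n = 3 each). The 96 h value was higher than that at 0 h by 0.14 on the log2 scale (limma, adjusted p = 0.0114). Esr1, the oestrogen receptor gene (mm10 chromosome 10, 4612046 to 5003761), was listed at 0 in each of the 4 Neo and Pax7 libraries. In the ER-Pax7 cells it read 1133 ± 27.2, 1118 ± 84.5, 1200 ± 97.3 and 1243 ± 27.8 scaled exon reads at 0, 12, 24 and 96 h (n = 3 each), with no called difference between times (limma over the 4 times, adjusted p = 0.0759).

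Constitutive Pax7 went with higher transcripts of melanotrope genes. Pcsk2, the prohormone convertase with which melanotropes cleave Pomc products to melanocyte-stimulating hormone (mm10 chromosome 2, 143546133 to 143816282), stood at 1.28 ± 0.0512 FPKM in Pax7 cells against 0.0719 ± 0.00182 in Neo cells (n = 2 each), an 8.0-fold difference. Oacyl, a gene of the acyltransferase family (mm10 chromosome 18, 65698268 to 65751537), reached 0.813 ± 0.0243 FPKM against 0.00523 ± 0.00739 (n = 2 each), and Megf11, which encodes a membrane protein with EGF-like repeats, 1.81 ± 0.00192 against 0.529 ± 0.0206. The level of Pomc itself (mm10 chromosome 12, 3954945 to 3960643) was 2356 ± 109 FPKM in Pax7 cells and 2499 ± 9.02 in Neo cells, a difference not called (log2 −0.09, SE 0.06; limma, adjusted p = 0.298). All folds are on the scale of log2(value + pseudocount), which understates the change of low genes.

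Beside Pcsk2 and Oacyl (log2 3.00 and 3.12), the largest rises in Pax7 cells were those of Zfp92, a zinc finger gene (log2 4.09, SE 0.08), and Iapp, which encodes the peptide hormone amylin (3.26, SE 0.07). They were followed by Lamb3, a laminin chain (3.00, SE 0.08), Mybpc1, a myosin-binding protein of slow muscle (2.85, SE 0.05), the imprinted gene Mest (2.46) and Apobec2 (2.37). Adjusted p-values of these 8 genes lay between 7.96e-04 and 0.00125 (limma). Pcsk2os2 (3.11) and Pcsk2os1 (2.88) were also called higher, but they lie on the strand opposite to Pcsk2 and counting did not use strand, so their reads and those of Pcsk2 cannot be told apart where they overlap. Among the largest falls were those of the chemokine receptor Cxcr4 (log2 −2.41, SE 0.12), the tyrosine-catabolic enzyme Hpd (−2.11), the lymphocyte adhesion gene Cd2 (−1.84) and the LIM homeobox gene Lhx1 (−1.74). S100a14 (−1.65), the kallikrein Klk1b9 (−1.58), Hspa12a (−1.54), the IGF-binding protein Igfbp4 (−1.53) and the sulfatase Arsg (−1.51) came next, and adjusted p-values of these 9 genes lay between 7.96e-04 and 0.00521 (limma).

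The 3 melanotrope markers tested, Pcsk2, Oacyl and Megf11, all rose (3 adjusted over the list alone). The list was called as a group (limma camera, adjusted p = 9.11e-04), a call lost at adjusted p = 0.732 with an estimated correlation. Its members were picked from what was known of Pax7, possibly in this cell line, so their direction is not independent evidence. Drd2, the dopamine receptor of melanotropes, was listed at 0 in each of the 4 libraries. Of 9 corticotrope markers, 1 rose and 4 fell (1 and 4 adjusted over the list alone; limma camera, adjusted p = 0.286). The convertase Pcsk1 rose (log2 0.74, SE 0.03; limma, adjusted p = 0.00195) and the glucocorticoid receptor Nr3c1 fell (−0.55, SE 0.04; limma, adjusted p = 0.00391). The corticotropin-releasing hormone receptor Crhr1 (−0.55; limma, adjusted p = 0.0143), Neurod1 (−0.20; 0.0270) and Pitx1 (−0.23; 0.0450) fell as well, while Tbx19 read 0.12 and Lifr −0.14 without a call. The Crhr1 call was lost without any 1 of the 4 libraries (limma, adjusted p = 0.0560 to 0.0716), that of Neurod1 without Neo 1, Pax7 1 or Pax7 2 (0.0722 to 0.121), and that of Pitx1 without Neo 1, Neo 2 or Pax7 1 (0.101 to 0.153). Of 6 pituitary progenitor genes, Sox9, Hes1 and Six6 were called higher and Sox2 lower, with no call for the list (limma camera, adjusted p = 0.881), and each of these 4 calls was lost without at least 2 of the 4 libraries.

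Genes of peptide processing and secretory granules were mostly higher in Pax7 cells: 13 of 20 rose and 1 fell (13 and 1 adjusted over the list alone), and the list was called (limma camera, adjusted p = 1.31e-04), with adjusted p = 0.732 with an estimated correlation. Besides Pcsk2 and Pcsk1, the granule-docking GTPase Rab27a (log2 1.13, SE 0.04) and chromogranin Chgb (0.90, SE 0.04) rose, and the granule adaptor Sytl4 fell (−0.65, SE 0.04; limma, adjusted p = 0.00312). Cell cycle genes went the other way. Of 25, 15 fell and 3 rose (15 and 3 adjusted over the list alone; limma camera, adjusted p = 9.11e-04; adjusted p = 0.732 with an estimated correlation), among them topoisomerase Top2a (−0.61, SE 0.04) and the mitotic genes Cdc20 (−0.40), Ccnb1 (−0.38) and Ccnb2 (−0.37), with limma adjusted p-values from 0.00391 to 0.00531. Of 22 genes of cholesterol synthesis and uptake, 14 rose and the other 8 did not pass (15 higher adjusted over the list alone; limma camera, adjusted p = 1.68e-04; adjusted p = 0.732 with an estimated correlation). Cyp51, a demethylase of sterol synthesis, rose by 0.62 on the log2 scale (SE 0.04), Dhcr7, the last reductase of that pathway, by 0.72 (SE 0.06), and the sterol carrier Stard4 by 0.80 (SE 0.07; limma, adjusted p = 0.00536). Of 16 neuronal adhesion and channel genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone; limma camera, adjusted p = 0.00671; adjusted p = 0.732 with an estimated correlation), led by the sodium channel Scn3a (1.88, SE 0.06; limma, adjusted p = 0.00139).

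In all, 4897 of 13393 genes tested differed between Pax7 and Neo cells at an adjusted p under 0.05 (limma), 2416 higher and 2481 lower in Pax7 cells (6576 at an unadjusted p under 0.05), and 289 of them by at least 2-fold (196 higher, 93 lower). The values of the groups did not overlap in 73.8% of all genes, where chance gives 33.3%. With library totals in place of TMM factors the split moved to 2600 higher and 1241 lower of 3841, or 67.7% higher against 49.3%. With Neo 1, Neo 2, Pax7 1 or Pax7 2 left out the count was 2205, 1980, 1577 or 1637, so small differences rest on having all 4 libraries: of 115 called members of the lists, 49 kept their call whichever library was left out, including 8 of 14 granule genes, 7 of 18 cell cycle genes, 8 of 14 cholesterol genes and 2 of 8 neuronal genes. The authors' deposited table lists 24 genes at an FDR under 0.05 for this comparison, 8 higher and 16 lower, and all 24 were also called here in the same direction.

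The induction experiment asked how early Pax7 acts. After 12 h of 4-hydroxytamoxifen, Oacyl stood at 32.7 ± 5.38 scaled exon reads against 1.59 ± 0.609 at 0 h (n = 3 each), a 13.2-fold rise on the pseudocount scale (log2 3.72, SE 0.14). Cilp, a cartilage matrix gene (mm10 chromosome 9, 65265180 to 65280605), rose 4.21-fold, from 38.5 ± 1.5 to 165 ± 6.10, and Pcsk2 1.27-fold, from 187 ± 6.63 to 238 ± 4.37. Tmem255b (log2 1.45), the lysosomal regulator Tfeb (1.39), the receptor Gprc5b (1.33) and Lmcd1 (1.21) completed the 6 largest rises. The largest falls were those of Tph1, which encodes the tryptophan hydroxylase of serotonin synthesis (−1.48, SE 0.13), Mgll, the monoglyceride lipase (−1.37, SE 0.14), Spon2 (−1.24), urate oxidase Uox (−1.21), Sec16b (−1.08) and the retinal reductase Dhrs3 (−1.0). Adjusted p-values of these 12 top genes ranged from 2.74e-16 to 3.50e-05 (limma).

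**Figure D1:**
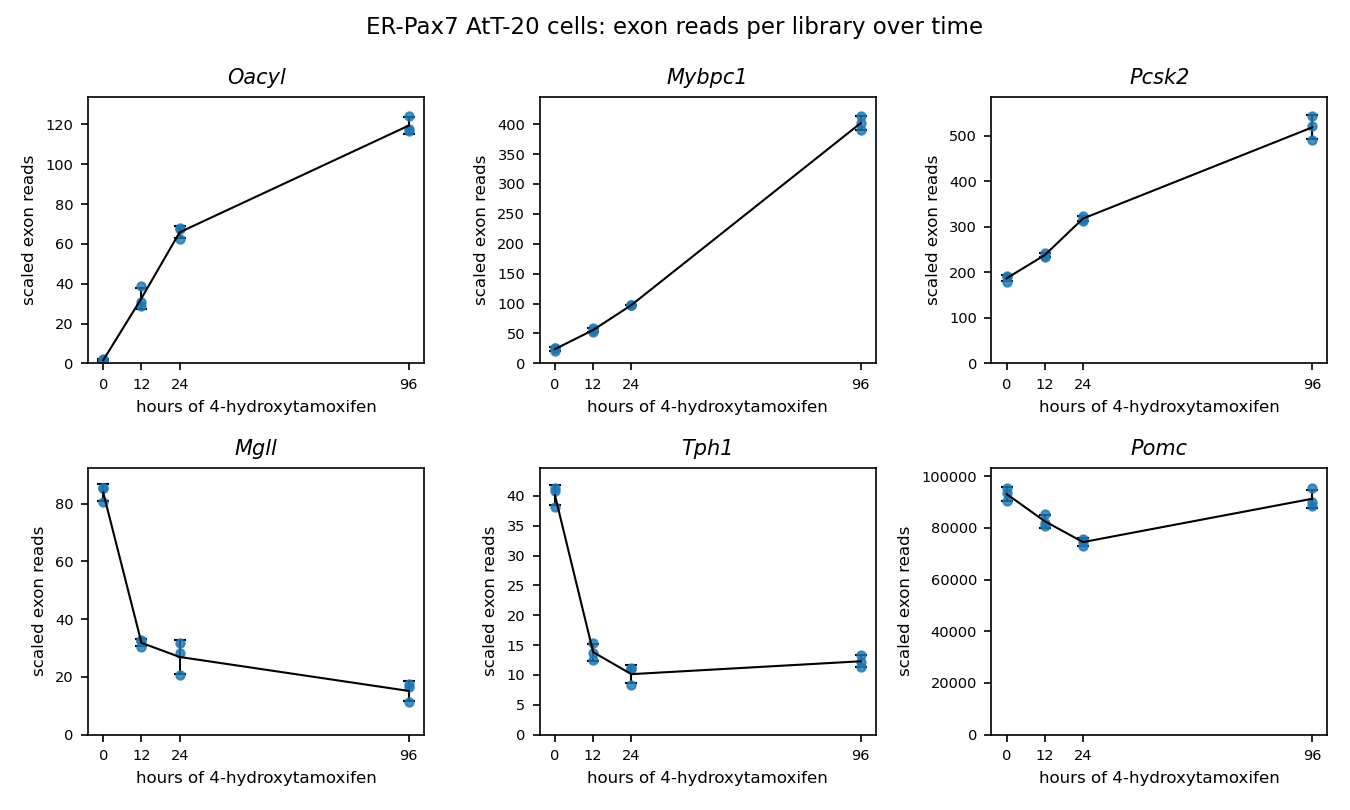
Scaled exon reads of Oacyl, Mybpc1, Pcsk2, Mgll, Tph1 and Pomc (vertical axes) against hours of 4-hydroxytamoxifen (horizontal axes) in ER-Pax7 cells. Points are single libraries and bars are mean ± SD of 3 libraries. Oacyl goes from 1.59 at 0 h to 32.7 at 12 h and 119.5 at 96 h, whereas Pomc is lowest at 24 h, at 74500.

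At 12 h, 2 of 4 melanotrope markers rose, Oacyl and Pcsk2 (2 adjusted over the list alone), and Megf11 (log2 −0.01) and Esm1 (−0.21) were not called. The list was called (limma camera, adjusted p = 3.75e-04), with adjusted p = 0.131 with an estimated correlation. Of 9 corticotrope markers 2 fell and the other 7 did not pass (4 lower adjusted over the list alone; limma camera, adjusted p = 0.0177; adjusted p = 0.131 with an estimated correlation). Crhr1 fell by 0.78 on the log2 scale (limma, adjusted p = 0.00108). Pcsk1 fell (−0.14), a call that ended without 0 h replicate 2 (−0.13; limma, adjusted p = 0.0572), and Pomc read −0.17 with no call (limma, adjusted p = 0.0577). Among genes of other pituitary lineages Gata2 fell (−0.34), a call lost without 0 h replicate 2 (−0.30; limma, adjusted p = 0.0554), and among progenitor genes Six6 (−0.21) and Sox2 (−0.30) fell, the call of Sox2 being lost without 0 h replicate 3 or 12 h replicate 2 (−0.27 in both, limma, adjusted p = 0.0524 and 0.0502). Neither of these lists was called (limma camera, adjusted p = 0.860 and 0.274).

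Cholesterol genes were lower by 12 h. Of 22, 15 fell and 1 rose (17 and 1 adjusted over the list alone; limma camera, adjusted p = 4.16e-12; adjusted p = 0.184 with an estimated correlation). They included Hmgcs1, an early enzyme of sterol synthesis (−0.48, SE 0.08; limma, adjusted p = 5.97e-04), and the isomerase Idi1 (−0.38, SE 0.06). Genes of the unfolded protein and amino acid stress response fell in 9 of 17 cases, and the other 8 did not pass (9 lower adjusted over the list alone; limma camera, adjusted p = 1.30e-10; adjusted p = 0.0568 with an estimated correlation). The chaperone Hspa5 (−0.29, SE 0.04), Creld2 (−0.32, SE 0.04) and the transcription factor Xbp1 (−0.22, SE 0.03; limma, adjusted p = 7.97e-05) were among them. Of 20 granule genes 9 fell and 2 rose (10 and 2 adjusted over the list alone; limma camera, adjusted p = 0.0262; adjusted p = 0.313 with an estimated correlation), with Rab27a higher (0.74, SE 0.04; limma, adjusted p = 1.99e-10) and Sytl4 lower (−0.34). Of 10 muscle genes 2 fell, of which the integrin Itga7 read −0.90 (SE 0.13; limma camera for the list, adjusted p = 0.0262; adjusted p = 0.184 with an estimated correlation). Of 7 oestrogen-response genes 2 fell (2 adjusted over the list alone), including Igfbp4 (−0.63, SE 0.04), and that list was called lower (limma camera, adjusted p = 0.00742), with adjusted p = 0.113 with an estimated correlation.

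At 12 h 991 of 15188 genes tested differed from 0 h at an adjusted p under 0.05 (limma), 429 higher and 562 lower, and 30 by at least 2-fold (17 higher, 13 lower). Groups did not overlap in 20.2% of all genes, where chance gives 10%. One library, 12 h replicate 2, held 2.35% of its reads on the ribosomal precursor Rn45s, against 0.753% to 1.26% in the others, and 871 genes were called without it. Of 16 called cholesterol genes 9, of 9 stress-response genes 7, and of 11 granule genes 6 kept their call whichever library was left out. The 5 granule calls lost, those of Chgb, Pcsk1, Ptprn, Scg2 and Vgf, were all falls.

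By 24 h Oacyl had reached 65.8 ± 3.07 scaled exon reads (log2 4.72 against 0 h), Cilp 262 ± 11.1 (2.73), Mybpc1 97.4 ± 0.420 against 23.7 ± 3.23 at 0 h (2.00) and Pcsk2 318 ± 5.4 (0.77; n = 3 each). Tmem255b (1.60), Gprc5b (1.42) and Wipf3 (1.42) were the other genes among the 6 largest rises. Tph1 (−1.89), Mgll (−1.63), Uox (−1.57), Dhrs3 (−1.32), Spon2 (−1.31) and the sodium pump regulator Fxyd3 (−1.24) fell most, and adjusted p-values of these 12 top genes ranged from 1.08e-18 to 7.76e-06 (limma). Pomc fell by 0.32 on the log2 scale (SE 0.05; limma, adjusted p = 2.24e-04), from 93090 ± 2663 to 74500 ± 1414 scaled exon reads.

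Of 4 melanotrope markers, Oacyl and Pcsk2 rose at 24 h (2 adjusted over the list alone; limma camera, adjusted p = 1.58e-04; adjusted p = 0.12 with an estimated correlation). Of 9 corticotrope markers 3 fell, Pomc, Crhr1 (−0.91) and Pcsk1 (−0.20), and Neurod1 rose (0.23), with 4 lower and 1 higher adjusted over the list alone and no call for the list (limma camera, adjusted p = 0.0544). In other hormone lineages Nr5a1 (−1.01) and Gata2 (−0.45) fell and the glycoprotein hormone subunit Cga was called higher (0.97), the last call being lost without 0 h replicate 3 or 24 h replicate 3 (0.85 and 0.67, limma, adjusted p = 0.0881 and 0.149). The cholesterol list held 18 lower genes and 1 higher gene of 22 (20 and 1 adjusted over the list alone; limma camera, adjusted p = 2.11e-16; adjusted p = 0.149 with an estimated correlation). Hmgcs1 fell from 4279 ± 241 to 2600 ± 440 scaled exon reads (n = 3 each; log2 −0.73, SE 0.08), and Cyp51 (−0.41) fell too (limma, adjusted p = 1.05e-05). Of 17 stress-response genes 11 fell and the other 6 did not pass (13 lower adjusted over the list alone; limma camera, adjusted p = 5.68e-09; adjusted p = 0.0932 with an estimated correlation), Sdf2l1 (−0.38) and Calr (−0.23) among them. Granule genes fell in 11 and rose in 4 of 20 cases (12 and 4 adjusted over the list alone; limma camera, adjusted p = 0.0101; adjusted p = 0.228 with an estimated correlation), chromogranins Chga (−0.37) and Chgb (−0.29) among the falls. Oestrogen-response genes fell in 3 of 7 cases (3 adjusted over the list alone; limma camera, adjusted p = 0.0133; adjusted p = 0.12 with an estimated correlation).

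In total 2059 genes differed at 24 h (limma, adjusted p under 0.05), 842 higher and 1217 lower, and 85 by at least 2-fold (34 higher, 51 lower), with no overlap of groups in 28.0% of all genes against 10% by chance. Of 19 called cholesterol genes 18 kept their call whichever library was left out.

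Oacyl, Mybpc1, Cilp and Pcsk2 were higher at 96 h than at any earlier time. Oacyl stood at 119.5 ± 4.06 scaled exon reads (47.5-fold over 0 h, log2 5.57), Mybpc1 at 401.5 ± 11.6 (16.4-fold, 4.04), Cilp at 428 ± 13.1 (10.9-fold, 3.44) and Pcsk2 at 518 ± 26.5 (2.77-fold, 1.47; n = 3 each). Lamb3 followed (log2 2.67, SE 0.08), then Klhl4 (2.02), Umodl1 (1.76), Wipf3 (1.71), the epidermal zinc finger gene Zfp750 (1.69), Lmcd1 (1.60) and Gprc5b (1.60). The largest falls were those of Mgll, to 15.1 ± 3.34 from 83.8 ± 2.91 (−2.42, SE 0.14), Fxyd3 (−2.27, SE 0.10), Lgi4 (−2.16), the T-type calcium channel Cacna1h (−2.15) and sarcolipin Sln (−1.85). The prolactin receptor Prlr (−1.77), Uox (−1.73), the potassium channel Kcnj1 (−1.72), Cd2 (−1.67) and Spock1 (−1.67) completed the 10 lowest, and adjusted p-values of all 20 top genes ranged from 1.04e-20 to 1.71e-07 (limma).

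Of 4 melanotrope markers 3 rose at 96 h (3 adjusted over the list alone; limma camera, adjusted p = 1.70e-04; adjusted p = 0.279 with an estimated correlation). The third beside Oacyl and Pcsk2 was Esm1 (0.85, SE 0.27; limma, adjusted p = 0.0177), whose call was lost without 0 h replicate 3 (0.66, 0.0933) or 96 h replicate 2 (0.80, 0.0618), and Megf11 read 0.09 with no call. Of 9 corticotrope markers 4 rose and 3 fell (4 and 3 adjusted over the list alone; limma camera, adjusted p = 0.936). The transcription factor Tbx19 (0.28), Neurod1 (0.31), Pcsk1 (0.14) and Pitx1 (0.25) rose, the call of Pitx1 being lost without 96 h replicate 1 (0.16, limma, adjusted p = 0.0578). Crhr1 (−0.54), Nr3c1 (−0.26) and Lifr (−0.26) fell, and Pomc was back at 91270 ± 3552 scaled exon reads (−0.03 against 0 h; limma, adjusted p = 0.720). Nr5a1 (−1.07) and Gata2 (−0.58) remained lower among genes of other lineages, as 2 of 4 tested (limma camera, adjusted p = 0.375). Of 9 progenitor genes Sox9 rose (1.15, SE 0.11) and Hes1 (−0.66), Six6 (−0.60) and Sox2 (−0.36) fell, without a call for the list (limma camera, adjusted p = 0.343).

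Cholesterol genes were less far below their 0 h levels at 96 h, with 12 of 22 lower and 2 higher (13 and 2 adjusted over the list alone; limma camera, adjusted p = 0.0467; adjusted p = 0.957 with an estimated correlation). The list was not called by fry at this time (limma fry, adjusted p = 0.238). Hmgcs1 remained lower (−0.59) while Stard4 (0.37) and Dhcr7 (0.32) were higher (limma, adjusted p = 2.01e-05). Stress-response genes fell in 8 and rose in 2 of 17 cases (8 and 2 adjusted over the list alone; limma camera, adjusted p = 0.0467; adjusted p = 0.482 with an estimated correlation), and Hspa5 was at its 0 h level (0.01). Granule genes were split, 7 higher and 7 lower of 20 (limma camera, adjusted p = 0.936): Rab27a (0.78) and the amidating enzyme Pam (0.27) rose, and Sytl4 (−0.78) and Chga (−0.45) fell. Among muscle genes 4 of 10 fell (limma camera, adjusted p = 0.0535), Itga7 furthest (−1.47, SE 0.13). Among neuronal genes 6 rose and 8 fell of 23 (limma camera, adjusted p = 0.936), with Scn3a (0.85) and Kcnma1 (0.59) higher. Of 25 cell cycle genes 4 rose and 4 fell (limma camera, adjusted p = 0.936), and of 7 oestrogen-response genes Greb1 rose (1.03, SE 0.15) and Igfbp4 fell (−1.46, SE 0.04; limma, adjusted p = 4.93e-16). That list's median (0.01) and mean (−0.04) differ in sign and it was not called (limma camera, adjusted p = 0.936). By fry, however, it was called lower (limma fry, adjusted p = 5.50e-07).

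**Figure D2:**
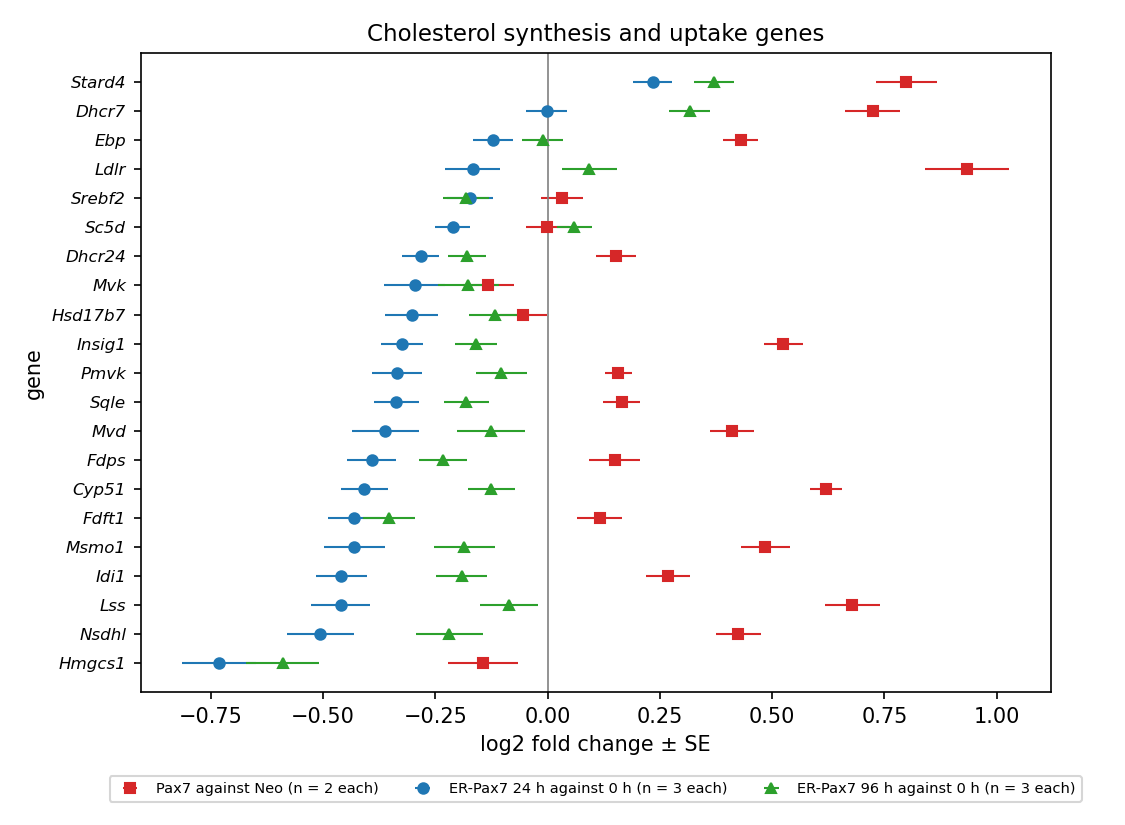
Log2 differences with SE (horizontal axis) of genes of cholesterol synthesis and uptake (vertical axis, 1 member not shown) for Pax7 against Neo (n = 2 each) and for ER-Pax7 at 24 and 96 h against 0 h (n = 3 each). Each point is 1 gene in 1 comparison. Medians of the whole list of 22 are 0.31 for Pax7 against Neo, −0.34 at 24 h and −0.17 at 96 h.

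At 96 h 5138 genes differed from 0 h (limma, adjusted p under 0.05), 2529 higher and 2609 lower, and 240 by at least 2-fold (102 higher, 138 lower). Groups did not overlap in 45.9% of all genes against 10% by chance, and the median size among called genes was 0.25 on the log2 scale. Time in culture and the compound itself run together with the induction here, since no library of cells without the fusion was treated.

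The steps between times showed where genes moved. From 12 to 24 h Oacyl (log2 1.0), Mybpc1 (0.80), Cilp (0.66), Lamb3 (0.58) and Pcsk2 (0.42) rose further, and Fabp2, an intestinal fatty acid-binding protein gene (−0.95), Igfbp4 (−0.30) and the annexin Anxa5 (−0.25) fell, with limma adjusted p-values from 1.08e-06 to 0.00241. These 8 were picked after their values were seen, as calls that held whichever library was left out. They were among 26 genes called (11 higher, 15 lower), of which 0 reached 2-fold (limma), and 1327 genes had an unadjusted p under 0.05. DESeq2 on recovered reads called 104 and edgeR 26. The count fell to 16 without 12 h replicate 1 and to 11 without 24 h replicate 1. Cholesterol genes had a median of −0.11 over this step (limma camera, adjusted p = 2.21e-10; adjusted p = 0.292 with an estimated correlation), with 8 lower adjusted over the list alone and no single member past the test over all genes.

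From 24 to 96 h, 1917 genes differed (943 higher, 974 lower; 18 by at least 2-fold; limma, adjusted p under 0.05), and 1267 without 96 h replicate 2. Pcsk2 (0.70) and Oacyl (0.85) rose again, and the melanotrope list was called (2 of 4 higher, 4 adjusted over the list alone; limma camera, adjusted p = 6.79e-05; adjusted p = 0.157 with an estimated correlation). Pomc (0.29), Pcsk1 (0.34) and Tbx19 (0.24) rose and Nr3c1 (−0.17) and Lifr (−0.18) fell, so that 3 of 9 corticotrope markers rose and 2 fell (5 and 2 adjusted over the list alone; limma camera, adjusted p = 0.0184; adjusted p = 0.157 with an estimated correlation). Of 22 cholesterol genes 15 rose and the other 7 did not pass (18 higher adjusted over the list alone; limma camera, adjusted p = 1.15e-10; adjusted p = 0.203 with an estimated correlation). Lss rose by 0.38 and Cyp51 by 0.28. Of 20 granule genes 8 rose, among them the neuropeptide precursor Vgf (0.35), and 1 fell (limma camera, adjusted p = 4.68e-04; adjusted p = 0.157 with an estimated correlation). Of 17 stress-response genes 6 rose and 3 fell (10 and 3 adjusted over the list alone; limma camera, adjusted p = 0.0103; adjusted p = 0.203 with an estimated correlation), including Hspa5 (0.23). Of the 15 cholesterol genes called here 5 kept their call whichever library was left out, namely Sc5d, Dhcr7, Lss, Cyp51 and Idi1. Of the 9 stress-response genes called here 3 did so.

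Across the 4 times together, 4629 of 15188 genes differed (limma F test, adjusted p under 0.05). A total of 768 genes were called at 12, 24 and 96 h in 1 direction, 342 higher and 426 lower, Oacyl, Cilp, Pcsk2, Mgll and Tph1 among them, while 3360 were called at 96 h and at neither earlier time. Of 102 genes at least 2-fold higher at 96 h, 77 were called higher at 24 h, and of 138 at least 2-fold lower 116 were called lower. The 3 comparisons share their 0 h libraries, which alone gives correlated differences. The correlation across genes between the 24 and 96 h differences was 0.792, where simulated unchanged groups gave 0.501, with a covariance of 0.0535 against 0.00695. For 12 and 24 h it was 0.797 against 0.502 (0.0318 against 0.00701), and for 12 and 96 h 0.681 against 0.501 (0.0374 against 0.00696). Genes called at 24 and 96 h in the same direction numbered 1714, 724 higher and 990 lower, against 140 and 209 for independent lists. For 12 and 24 h they were 378 higher and 510 lower against 23.8 and 45.0 for independent lists, and for 12 and 96 h 360 and 447 against 71.4 and 96.5. The 3 controls were not divided between the comparisons, so part of the excess may come from the shared controls.

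The last comparison asked how far the constitutive and the induced system moved alike. Oacyl, Mybpc1, Lamb3 and Pcsk2 rose and Igfbp4, Cd2 and Itga7 fell in both. Of 12992 genes tested in both tables, 1024 were higher with constitutive Pax7 and at 96 h of induction, where independent lists would share 431 (odds ratio 5.28, one-sided Fisher's exact test, p = 7.95e-227). Another 1007 were lower in both against 429 (odds ratio 5.10, one-sided Fisher's exact test, p = 1.13e-216), and 282 were called in opposite directions. Among genes changed at least 2-fold in both, 44 were higher and 22 lower in both and 1, Iapp, went opposite ways. The Spearman correlation of the differences across genes was 0.455 at 96 h, 0.330 at 24 h and 0.269 at 12 h. Genes are not independent replicates, so the correlation is a description, and the p-values of Fisher's exact test do not measure replication over libraries. Whether a gene's change differed between the systems was not tested, because exons were counted in one table and gene bodies in the other.

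**Figure D3:**
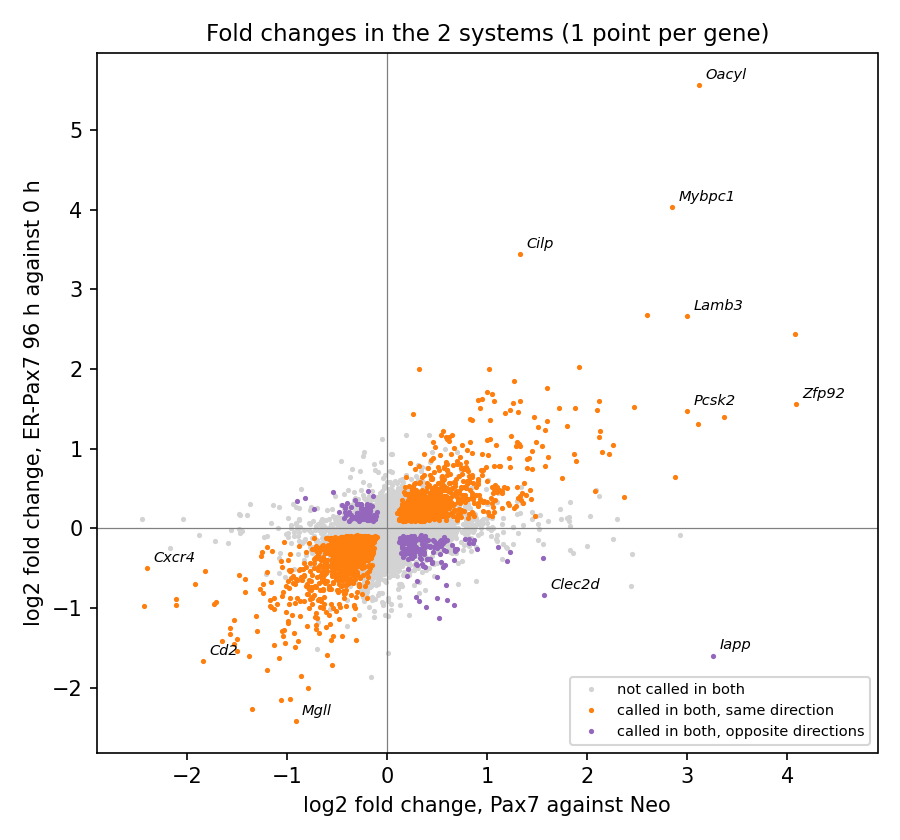
Log2 difference of ER-Pax7 96 h against 0 h (vertical axis, n = 3 each) against that of Pax7 against Neo (horizontal axis, n = 2 each). Each point is 1 of the genes tested in both tables, with Pax7 itself left out. Oacyl lies at 3.12 and 5.57 and Iapp at 3.26 and −1.60.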

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

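Every difference between the systems named in this part, and the tests of library scaling and of 4-hydroxytamoxifen, were chosen only after the values were seen; the test of intron reads was written before.

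Among 282 genes called in opposite directions by constitutive Pax7 and by 96 h of induction, 6 changed by at least 0.5 on the log2 scale without overlap of the groups in each, and whether the changes differ was not tested. Iapp, the amylin gene, read 3.26 for Pax7 against Neo and −1.60 at 96 h against 0 h. Its levels went from 0.411 ± 0.0394 to 4.78 ± 0.0715 FPKM (n = 2 each) in the first and from 48.4 ± 3.53 to 15.4 ± 2.94 scaled exon reads (n = 3 each) in the second. Calca, which encodes calcitonin and its related peptide, read 0.59 and −0.90. The lectin gene Clec2d read 1.56 and −0.84, the neurotrophin receptor Ntrk3 0.59 and −0.71, the kinase anchor gene Sphkap 0.67 and −0.97, and the clone gene AU021092 0.52 and −1.12. The calls for Pax7 against Neo were lost with a library left out for Calca (up to limma adjusted p = 0.123), Ntrk3 (0.0627) and AU021092 (0.0528), with folds about as large.

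Cholesterol genes stood out because the list's mean was 0.32 for Pax7 against Neo and −0.32 at 24 h of induction, a difference not tested. Library scaling did not make it: under 3 scalings the list's median moved by at most 0.0758 from 0.31 in the first comparison and −0.34 in the second. Intron reads, counted in the Neo and Pax7 table and not in the other, cannot be told apart from a change of mature transcripts. The 11 members with the larger share of exon bases had a median of 0.346 (SE 0.111), but exons made up only 17.3% to 42.1% of their gene bodies. The compound itself cannot be told apart from the induction, because 0 libraries of cells without the fusion were treated. A sustained against a recent exposure to Pax7, or a difference between the cell populations, could also lie behind it and was not tested. The granule list was also called in opposite directions, with medians of 0.287 for Pax7 against Neo and −0.128 at 24 h. These calls (limma camera, adjusted p = 1.31e-04 and 0.0101) were lost with an estimated correlation (0.732 and 0.228), and that difference was not tested either.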

How the results depend on the processing

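The pseudocounts, edgeR on recovered reads, the fits without Rn45s, the fits without 12 h replicate 2 where 12 h is not compared, and the alternatives for the overlap other than its fold minimum were chosen after seeing the data. The others were fixed before, though the values of the filters were set once the units were known. No gene or list tallied reversed its direction. The counts compared here are totals of both directions. Within the total for Pax7 against Neo, library totals moved the balance toward higher genes, as given above. With median-of-ratios scaling, library totals, either other pseudocount, the stricter filter, edgeR or DESeq2, each total of called genes stayed within 1.5 times its value, except 104 genes for 24 h against 12 h with DESeq2 (26 otherwise). That comparison also gave 17 without the filter on low values, 16 with only the groups compared in the fit, and 11 to 31 with 1 library left out, lowest without 24 h replicate 1 and highest without 24 h replicate 3. The cause was not tested. Requiring 2-fold left 289 genes for Pax7 against Neo, 30, 85 and 240 for 12, 24 and 96 h, 0 for 24 h against 12 h (limma; 1327 at an unadjusted p under 0.05, and 26 by edgeR and 104 by DESeq2 with no minimum fold), 18 for 96 h against 24 h, 249 over the 4 times and 66 genes shared by both systems. Leaving out 1 library gave 1577 (Pax7 1) to 2205 (Neo 1) of 4897 genes for Pax7 against Neo, where the lone library is assumed to vary like the other group and fewer samples lower the count; 1501 to 2064 of them were called with all 4. For 96 h against 24 h it gave 1267 (without 96 h replicate 2) to 2123, and for 12 h, 24 h, 96 h and all times 700 to 889, 1458 to 2200, 4150 to 5323 and 3559 to 4771. The values 2123, 2200 and 5323 are fits without 12 h replicate 2, the library doubted for its share of Rn45s. Of 142 gene results tallied (the top genes and leading list members, not every gene named), 130 kept their call without any library of the groups compared and 12 lost it in at least 1 such fit. Other calls lost are given with their genes. Median-of-ratios scaling changed the call of none of the 142, and DESeq2 of none of the 99 it covers.

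Lists called by camera with the preset correlation numbered 5, 7, 6, 3, 6 and 8 (Pax7 against Neo, 12, 24 and 96 h against 0 h, 24 h against 12 h, 96 h against 24 h). With an estimated correlation they numbered 0, 0, 0, 0, 0 and 0, and with fry, which asks only whether a list's genes move 1 way, 11, 8, 12, 9, 1 and 13. The muscle list from 24 to 96 h was also lost with median-of-ratios scaling (limma camera, adjusted p = 0.0514, against 0.0487 with TMM) and kept by fry (limma fry, adjusted p = 0.00852). For 96 h against 0 h, fry called lower several lists that camera did not call. These were the other-lineage, progenitor, muscle, oestrogen-response, Notch, epithelial and immune lists (limma fry, adjusted p = 5.50e-07 to 0.0183).

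Replicate numbers are shared by the groups, but the labels tie them to no common culture or day. Of 18 pairs of ER-Pax7 libraries with a common number 15 had a correlation of deviations over 0.1 (−0.26 to 0.548), and 11 of 12 libraries were closest to their own number, a hint from the data only; the Neo and Pax7 pair gave −0.00824. With the replicate block the counts were 3450 for Pax7 against Neo, 1273, 2526 and 5766 for 12, 24 and 96 h, 54 for 24 h against 12 h (26 without it; the cause was not tested), 2505 for 96 h against 24 h, 5454 over all times and 1651 shared by both systems. Of the same 142 gene results 4 lost their call under it, among them Neurod1, Pitx1 and Hes1 for Pax7 against Neo, as did the muscle list from 24 to 96 h (limma camera, adjusted p = 0.0616). Planned but not run were the test of a difference between the systems, which needs the same counting in both tables, and DESeq2 for Pax7 against Neo and in both systems for the overlap, which needs counts. Depth limits the lowest genes: 1 read is worth 0.0813 to 0.118 scaled exon reads, below the minimum of 1 for testing.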

Other observations

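The lists described first were fixed before the data were examined, while the patterns of genes low at 24 h and of the Pcsk2 antisense genes, and the tests of the 24 h libraries alone, of their division between the steps and of both antisense genes, were chosen only after the values were seen.

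With constitutive Pax7, 9 of 17 genes of the unfolded protein and amino acid stress list rose and 3 fell (9 and 4 adjusted over the list alone; limma camera, adjusted p = 0.25). The chaperones Hspa5 (log2 0.68), Hsp90b1 (0.59) and Calr (0.43) and the glutathione-degrading enzyme Chac1 (0.60) rose, whereas Ddit3, a transcription factor of cell stress (−0.67), and the pseudokinase Trib3 (−0.57) fell. Of 12 Notch genes 3 rose and 3 fell (4 and 3 adjusted over the list alone; limma camera, adjusted p = 0.815), with the target Hey1 (1.30) and the ligand Dll1 (0.74) higher. Dll1 also rose at 12 h (0.60), 24 h (0.85) and 96 h (0.76), where Lfng, which modifies Notch, fell (−0.72; list 2 higher and 4 lower of 15; limma camera, adjusted p = 0.138). Interferon genes fell in 3 of 11 cases with constitutive Pax7 (5 lower adjusted over the list alone; limma camera, adjusted p = 0.228), among them Irf7 (−0.54) and Usp18 (−0.61), and in 5 of 15 cases at 24 h (limma camera, adjusted p = 0.0133; adjusted p = 0.346 with an estimated correlation). Irf7 (−0.33) was the 1 of those 5 whose call held whichever library was left out. From 24 to 96 h 4 interferon genes rose (6 adjusted over the list alone; limma camera, adjusted p = 0.00507; adjusted p = 0.203 with an estimated correlation), among them Mx1 (0.63) and Irf7 (0.33), while 3 of 15 Notch genes fell (limma camera, adjusted p = 0.0103; adjusted p = 0.157 with an estimated correlation), Lfng furthest (−0.48).

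Epithelial genes moved both ways: with constitutive Pax7 the claudins Cldn4 (1.86) and Cldn3 (0.42) rose among 4 higher and 2 lower of 11 (limma camera, adjusted p = 0.519), and at 96 h 6 of 16 fell and 1 rose (limma camera, adjusted p = 0.138), led by the epithelial factor Grhl2 (−0.88). Of the immediate early genes Egr2 rose with constitutive Pax7 (0.81; 4 higher and 1 lower of 14; limma camera, adjusted p = 0.342), and Nr4a2 fell at 12 h (−0.56), 24 h (−0.61) and 96 h (−0.44), when Ier3 rose (0.78; 4 higher and 3 lower of 15; limma camera, adjusted p = 0.936). Thbs1, a matrix glycoprotein, rose with constitutive Pax7 (1.01) and at 96 h (0.92), with 1 matrix gene higher and 1 lower of 7 at that time (limma camera, adjusted p = 0.936). The macrophage lysozyme Lyz2 was lower in Pax7 cells (−1.27), where Cd68 was called higher (0.77), a call lost without either Neo library. Lyz2 was also lower at 96 h (−0.34), the 1 called of 4 immune genes there (limma camera, adjusted p = 0.633). Among cyclin-dependent kinase inhibitors Cdkn1b rose (0.37) and Cdkn1c fell (−0.39) with constitutive Pax7 (1 higher and 3 lower of 6; limma camera, adjusted p = 0.342). Of 8 muscle genes Itga7 (−1.13) and Eya1 (−0.35) fell there and Des rose (0.94; limma camera, adjusted p = 0.962), the calls of Eya1 and Des being lost without some library. From 24 to 96 h 3 of 10 muscle genes fell (limma camera, adjusted p = 0.0487; adjusted p = 0.203 with an estimated correlation; 0.0514 and no call with median-of-ratios scaling). Oestrogen-response genes had a median of 0.16 and a mean of −0.165 in Pax7 against Neo, signs that differ, with 2 higher and 1 lower of 5 (limma camera, adjusted p = 0.541). Chromatin regulators (2 higher and 3 lower of 20; limma camera, adjusted p = 0.936) and Wnt genes (1 higher of 8; limma camera, adjusted p = 0.936) were not called at 96 h. From 12 to 24 h, where few single genes were called, the granule, cell cycle, immediate early and interferon lists were called lower (limma camera, adjusted p = 0.0458, 0.0458, 0.0321 and 0.0176; adjusted p = 0.292 with an estimated correlation for each). Fry called none of these lists (limma fry, adjusted p = 0.175, 0.156, 0.156 and 0.202). Pcsk2 was the only member called, and it rose. The melanotrope list was called higher over this step by camera (limma camera, adjusted p = 1.21e-05, and 0.183 with an estimated correlation). Fry called it too (limma fry, adjusted p = 0.0165).

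A total of 124 genes were lower at 24 h than at 0 h and higher at 96 h than at 24 h, and 41 did the reverse (limma, adjusted p under 0.05 for both steps). The low genes include Pomc and 12 of the 22 cholesterol genes. At 12 h 69.1% of the fall was already present (SE 3.88 over genes, median −0.17 then and −0.25 at 24 h, from the mean of 0 h and 96 h). Equal chance in the 0 h, 24 h and 96 h libraries would give 33.3%. Chance in the 0 h and 96 h libraries alone would lower 12 h and 24 h alike, and the SE leaves out error shared by genes. The share therefore does not decide whether something in the 24 h libraries alone was the cause. With the 24 h libraries divided between the steps in 6 ways, 34 to 67 genes were low though no library served both steps. Independent steps would give at most 4.19 by chance. Both steps share 1 estimate of each gene's spread and genes move together, so chance could give more than that. How much more was not tested. Simulated unchanged libraries gave 0 genes in either direction against 165, which decides nothing, since little is called where no gene changes. A passing response to the compound or to medium change, or an early phase of the Pax7 response, could lie behind it, and the design cannot set them apart; the number of low genes was 121 with median-of-ratios scaling and 94 with library totals.

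Pcsk2os1 and Pcsk2os2, annotated on the strand opposite to Pcsk2, rose with it. Pcsk2os2 lies inside Pcsk2, and its FPKM was 1 to 1.1 times that of Pcsk2 in the 4 Neo and Pax7 libraries, which suggests that it holds reads of Pcsk2. Whether the rise of Pcsk2os1, which shares 1705 bases (13.8%) with Pcsk2, comes from reads of Pcsk2 cannot be told apart: its log2 change at 96 h was smaller than that of Pcsk2 by 0.827 (SE 0.101), which Pcsk2 reads on top of a steady level of its own would also give. No biological explanation was tested.

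Other splits of the libraries were counted for each comparison of at least 3 libraries a group. For 12, 24 and 96 h against 0 h and 96 h against 24 h, 1 of 10 splits gave as many genes as the real one (991, 2059, 5138 and 1917), and the highest other split gave 0 in each; 10 splits are too few for a share under 0.05. For 24 h against 12 h 2 of 10 did, with 26 genes in the real split and 211 in the highest other, again too few splits for such a share. That split set 12 h replicates 1 and 3 and 24 h replicate 3 against 12 h replicate 2 and 24 h replicates 1 and 2, which points to a structure of the samples beside time. Over the 4 times 2 of 100 splits, counting the real one, called as many genes as the real one (4629), a share under 0.05. These splits ignored the replicate numbers, and replicates may not be separate cultures, so the share does not exclude chance. The highest other split, with 4842, kept 0 h and 96 h whole and mixed 12 and 24 h.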
